A study of Mus musculus with 12 samples.

How the data were processed

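Chromatin immunoprecipitation with sequencing (ChIP-seq) was analysed from 12 libraries of mouse embryonic stem cells. Per the labels, the cells were grown in serum with LIF and carried either an empty expression vector or the same vector encoding netrin-1. Each cell line was profiled with an antibody against H3K4me3 and an antibody against H3K27me3, with 3 libraries per cell line and mark. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

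The authors deposited 4 tables of coverage signal, each an average profile around the centres of a set of sites. Per the file headers, every table has 6 coverage columns, 1 per library, so replicates were not pooled. The mark and the site class (serum bivalent, here called bivalent, or not bivalent) are given by the names of the tables. Each column name gives the cell line and the replicate. The 3 tables that reach 4000 bp to each side have 801 bins spaced 10 bp apart. The table of H3K27me3 at non-bivalent sites reaches 25000 bp to each side and has 251 bins spaced 200 bp apart. The submitters' processing notes name BWA, Picard, MACS2 and HOMER and the mouse build mm9, with no versions. How the sites were chosen, whether duplicate fragments were removed and how the coverage was scaled are not given in the sources used here. The tables hold averages over sites, so no single site, coordinate or gene was analysed here. Strand-specific tag densities were not analysed here.

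The scaling was examined from the values. In all 24 columns, 100% of the values were whole multiples of a column-specific step, to within a tolerance of 0.02 of a step. The steps were then compared with those that HOMER would give when it scales to 10 M tags and to fragments of 100 bp. Numbers of sites from 500 to 20000 and fragment lengths from 190 to 225 bp were searched, with scaling factors in whole hundredths up to 60 hundredths. Of these, 1 number of sites, 2590, fitted all 12 columns at bivalent sites. The same library factors then gave 22595 sites for H3K4me3 at non-bivalent sites and 10985 for H3K27me3 at non-bivalent sites. For the 10 libraries with a single solution, the inferred fragment lengths were 204 to 210 bp and the inferred totals 34.5 to 47.6 M tags. Vector H3K4me3 replicate 3 had several solutions, all between 27.0 and 31.2 M tags, and netrin-1 H3K27me3 replicate 1 had solutions between 35.7 and 41.7 M tags. Site numbers, fragment lengths and totals are inferences from the values under that scaling, not stated quantities. Under it, the counting error of a mean bin of the central window was at most 0.434%. That error covers counting only and is far below the spread between libraries.

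For each library, the mean coverage was taken over a central window, and the flank level over the outermost bins on both sides. The central window reached 1000 bp to each side for H3K4me3, 2000 bp for H3K27me3 at bivalent sites and 5000 bp for H3K27me3 at non-bivalent sites. The flank was the outermost 500 bp, or 5000 bp in the wide table. Changes are log2 ratios of the mean over the netrin-1 libraries to the mean over the vector libraries. They were tested with two-sided exact permutation tests of the library labels. With 3 libraries against 3 there are 20 arrangements, so the smallest possible p is 0.1 and no such comparison can pass 0.05. Differences between site classes used joint permutations of the same libraries. The difference between marks used permutations within each mark (400 arrangements, smallest p 0.005), which treats the libraries of the 2 marks as independent. That last test takes as its null hypothesis no difference in either mark, so a real change in 1 mark widens its reference distribution. Benjamini-Hochberg adjustment was made over the 4 main tests and over the 3 tests of differences. On simulated data with no effect, 10.8% of 500 comparisons of 3 against 3 gave p of 0.1 or less, and 4.4% of 500 differences between marks gave p of 0.05 or less. No 2 columns of a table shared a value in any bin.

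Libraries of the 2 cell lines share replicate numbers. The deviations of same-numbered H3K27me3 libraries from their group means correlated across bins at 0.695, 0.399 and 0.930 for replicates 1, 2 and 3, all above the threshold of 0.1 that was set for pairing, so these numbers were taken as pairs in an alternative test. Vector replicate 2 and netrin-1 replicate 1, with different numbers, correlated at 0.916, so the pairing is a hint from the values and not part of the stated design. For H3K4me3 the correlations were 0.970, -0.908 and 0.891, so the numbers do not pair those libraries. The paired alternative is an exact sign-flip test, whose smallest p with 3 pairs is 0.25.

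Windows, flanks, tests and most alternatives were fixed before the data were examined. The alternatives were subtraction of the flank, division by the flank, other window widths, the highest bin, each side of the centre, each library left out and the replicate pairing. The rule for named genes was to name none where the tables carry no gene names. The items named are therefore the site classes and distance ranges. The distance ranges, the tests of profile shape and of the flanks, and windows without the bins from -350 to 150 bp, were chosen after the profiles had been seen. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.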

Results

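Histone H3 lysine 4 trimethylation (H3K4me3), a mark of active promoters, and lysine 27 trimethylation (H3K27me3), the mark deposited by Polycomb repressive complex 2, were profiled by ChIP-seq in mouse embryonic stem cells. Netrin-1 is a secreted, laminin-related guidance protein. Cells expressing a netrin-1 transgene were compared with cells carrying the empty vector. Bivalent sites carry both marks and in embryonic stem cells lie mostly at promoters of developmental genes that are silent or weakly expressed. Coverage was available as averages around the centres of bivalent sites and of sites of each mark that the table names class as not bivalent. Each of the 4 groups (2 marks in 2 cell lines) held 3 libraries. The values are scaled fragment coverage per site. The scaling implied about 34.5 to 47.6 M tags for the 10 libraries in which it could be solved uniquely. The inferred numbers of sites were 2590 bivalent sites, 22595 non-bivalent H3K4me3 sites and 10985 non-bivalent H3K27me3 sites.

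**Figure D1:**
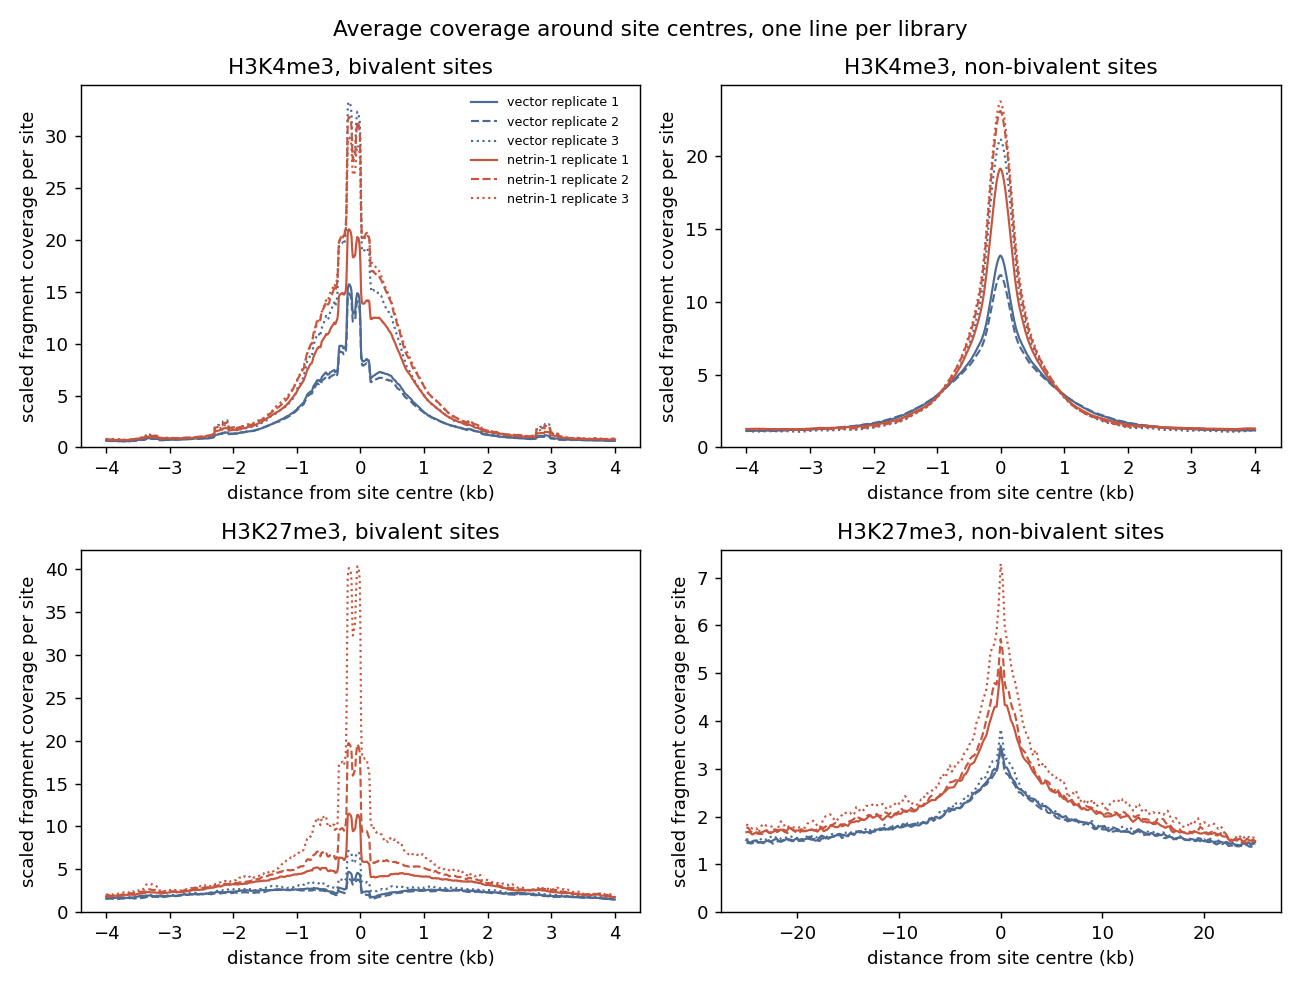
Average scaled fragment coverage per site (y axis) against distance from the site centre in kb (x axis), with 1 line per library, vector in blue and netrin-1 in red, and line styles for replicates 1 to 3. The H3K27me3 lines of all 3 netrin-1 libraries run above those of all 3 vector libraries at both site classes, whereas the highest H3K4me3 bin of vector replicate 3 lies above all 3 netrin-1 libraries at bivalent sites (33.3 against at most 31.9) and within their range at non-bivalent sites (21.1 against 19.1 to 23.7).

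The first question was whether H3K27me3 at bivalent sites differed in cells expressing netrin-1. Mean coverage within 2000 bp of the centre was 2.72 ± 0.356 (SD, n = 3) in vector cells and 6.50 ± 2.22 (SD, n = 3) in netrin-1 cells, a ratio of 2.39. All 3 netrin-1 libraries, from 4.57 to 8.93, lay above all 3 vector libraries, which ranged from 2.44 to 3.12. The log2 ratio was 1.26, with an exact two-sided permutation p of 0.1, the smallest that 3 libraries against 3 can give, and 0.2 after adjustment over the 4 main comparisons. The difference in means exceeded the SD of either group but not the span of the netrin-1 libraries. The design cannot take the comparison past 0.05.

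The H3K27me3 difference at bivalent sites depended on distance. Within 250 bp of the centre, coverage was 3.47 ± 1.03 (SD, n = 3) in vector cells and 14.9 ± 8.73 (SD, n = 3) in netrin-1 cells, a log2 ratio of 2.10. Between 500 and 1000 bp the ratio of the means was 2.30. Between 1000 and 2000 bp the log2 ratio was 0.71. Between 3500 and 4000 bp, coverage was 1.67 ± 0.062 (SD, n = 3) in vector cells and 2.06 ± 0.109 (SD, n = 3) in netrin-1 cells, a log2 ratio of 0.30. In all 6 distance ranges every netrin-1 library lay above every vector library (exact permutation p = 0.1 each, 0.16 after adjustment over the 24 ranges of the 4 tables). Chance gives such a complete separation, in either direction, in 10% of comparisons.

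The bivalent H3K27me3 profile had a narrow double maximum, with 1 summit near -190 bp and another near -50 bp. At -190 bp, coverage ranged from 3.88 to 7.13 in the vector libraries and from 11.5 to 39.9 in the netrin-1 libraries. The H3K4me3 profile of the same sites had the same narrow feature. Without the bins from -350 to 150 bp, the log2 ratio within 2000 bp was 0.996 for H3K27me3, and the cell lines remained fully separated (exact permutation p = 0.1). The width of the H3K27me3 profile midway between flank and maximum is that of the narrow feature. It was 210 bp in all 3 vector libraries and 230 bp in all 3 netrin-1 libraries (exact permutation p = 0.1). The bins were 10 bp apart, and the inferred fragment lengths were 204 to 210 bp in the 10 libraries with a single solution. The width is thus close to 1 fragment length and does not describe the broader H3K27me3 signal. The log2 ratio was 2.08 after subtraction of the flank and 2.19 for the highest bin. In vector cells, central coverage was 1.62 ± 0.150 times the flank (SD, n = 3), against 3.12 ± 0.897 in netrin-1 cells. Subtraction therefore leaves a small base in vector cells, which enlarges the log2 ratio. Leaving out 1 library at a time moved the log2 ratio of the central window between 0.96 and 1.46. The highest bin lies in the narrow feature, which the range within 250 bp also covers.

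**Figure D2:**
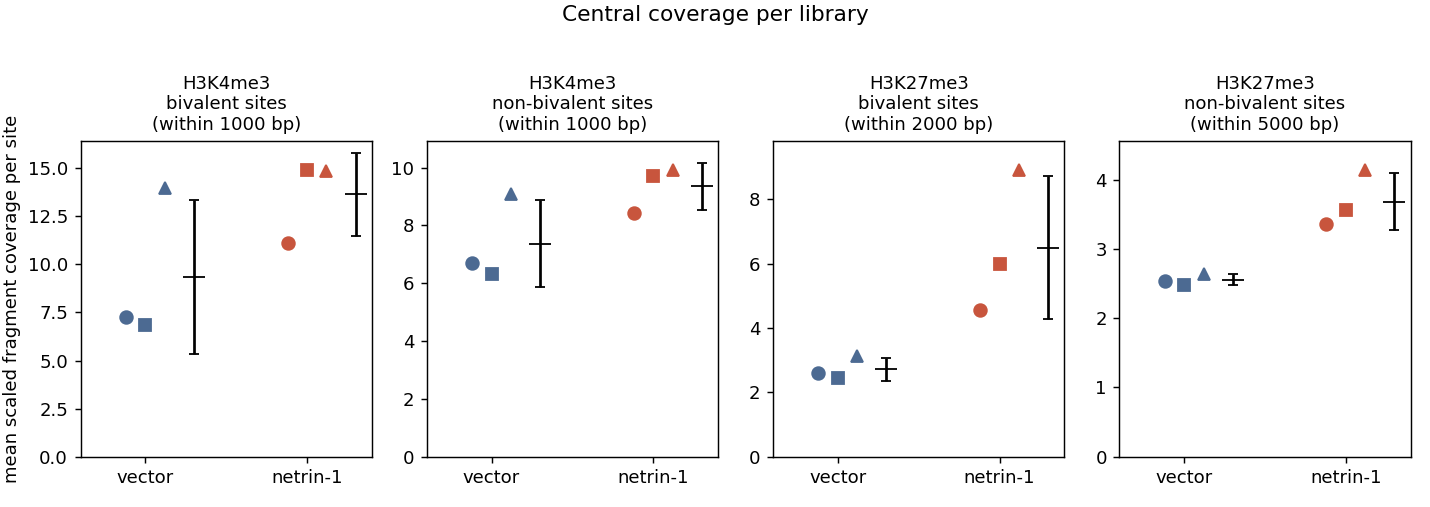
Mean scaled fragment coverage per site in the central window (y axis, starting at 0) for vector and netrin-1 cells, with 1 panel per mark and site class. Circles, squares and triangles are replicates 1, 2 and 3, and the black mark and bar are the mean and SD of 3 libraries. H3K27me3 values of the cell lines do not overlap, whereas for H3K4me3 the vector replicate 3 value lies above netrin-1 replicate 1.

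H3K27me3 at non-bivalent sites was compared in the same libraries. Mean coverage within 5000 bp was 2.55 ± 0.080 (SD, n = 3) in vector cells and 3.68 ± 0.411 (SD, n = 3) in netrin-1 cells, a ratio of 1.44 and a log2 ratio of 0.53. The netrin-1 libraries ranged from 3.35 to 4.14 and the vector libraries from 2.48 to 2.64, again without overlap (exact permutation p = 0.1, adjusted p = 0.2). The profile was broad and centred at 0 bp in all 6 libraries. The log2 ratio was 0.71 within 1000 bp of the centre, 0.30 between 5000 and 10000 bp, and 0.17 in the flank between 20000 and 25000 bp. The width of the profile midway between flank and maximum was 4600 ± 529 bp (SD, n = 3) in vector cells and 3533 ± 306 bp (SD, n = 3) in netrin-1 cells (exact permutation p = 0.1). The log2 ratio of the central window was 0.90 after subtraction of the flank and 0.33 over the whole profile.

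Site classes were then compared within H3K27me3, where library scaling cancels. The log2 ratio at bivalent sites exceeded that at non-bivalent sites by 0.73 (exact permutation p = 0.1, the smallest possible, and 0.3 after adjustment over 3 tests of differences). Per library, the log2 ratio of bivalent to non-bivalent coverage was 0.04, -0.03 and 0.24 in vector replicates 1, 2 and 3, and 0.45, 0.75 and 1.11 in netrin-1 replicates 1, 2 and 3. The classes differed in window (2000 and 5000 bp to each side), in bin spacing and in their sites, so the level of this ratio was not interpreted. Only its difference between the cell lines was used. With a window of 2000 bp to each side in both classes the difference was 0.60, and without the bins from -350 to 150 bp it was 0.47 (exact permutation p = 0.1 for both). It was 1.18 after subtraction of the flank and 1.43 for the highest bin.

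For H3K4me3 at bivalent sites, mean coverage within 1000 bp was 9.36 ± 4.0 (SD, n = 3) in vector cells and 13.6 ± 2.18 (SD, n = 3) in netrin-1 cells, a log2 ratio of 0.54 (exact permutation p = 0.2, adjusted p = 0.2). The groups overlapped, and the difference was about the size of the vector SD. Vector replicates 1 and 2 were at 7.26 and 6.85, while vector replicate 3 was at 14.0, above netrin-1 replicate 1 at 11.1. Without vector replicate 3 the log2 ratio was 0.95 (exact permutation p = 0.1), and without vector replicate 2 it was 0.36 (exact permutation p = 0.5). Divided by the flank it was 0.33 (exact permutation p = 0.4). The H3K4me3 groups did not overlap in 2 of the 6 distance ranges (exact permutation p = 0.1 each, 0.16 after adjustment over the 24 ranges), the flank and the range from 1000 to 2000 bp. In the latter, coverage was 2.37 ± 0.424 (SD, n = 3) in vector cells and 3.15 ± 0.234 (SD, n = 3) in netrin-1 cells, while the groups overlapped in the ranges on either side of it. The width of the profile midway between flank and maximum was 480 ± 10 bp (SD, n = 3) in vector cells. In netrin-1 cells it was 837 ± 180 bp (SD, n = 3), without overlap (exact permutation p = 0.1). The maximum lies in the narrow feature, so this width depends on the height of that feature over the coverage around it. It is not a measure of how far the broader H3K4me3 signal reached.

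H3K4me3 at non-bivalent sites formed a single symmetric maximum within 10 bp of the centre in every library. Mean coverage within 1000 bp was 7.37 ± 1.50 (SD, n = 3) in vector cells and 9.35 ± 0.815 (SD, n = 3) in netrin-1 cells, a log2 ratio of 0.34 (exact permutation p = 0.2, adjusted p = 0.2). Vector replicate 3, at 9.09, again lay above netrin-1 replicate 1, at 8.42, and without it the log2 ratio was 0.52 (exact permutation p = 0.1). The log2 ratio was 0.50 within 250 bp and -0.09 between 1000 and 2000 bp, where coverage was 2.32 ± 0.186 (SD, n = 3) in vector cells and 2.18 ± 0.057 (SD, n = 3) in netrin-1 cells (exact permutation p = 0.4). The central log2 ratio was 0.21 both after division by the flank and over the whole profile. The width midway between flank and maximum was 630 ± 75.5 bp (SD, n = 3) in vector cells and 537 ± 5.77 bp (SD, n = 3) in netrin-1 cells. The groups did not overlap (exact permutation p = 0.1), but only narrowly. The narrowest vector library was at 550 bp and the widest netrin-1 library at 540 bp, with bins 10 bp apart.

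**Figure D3:**
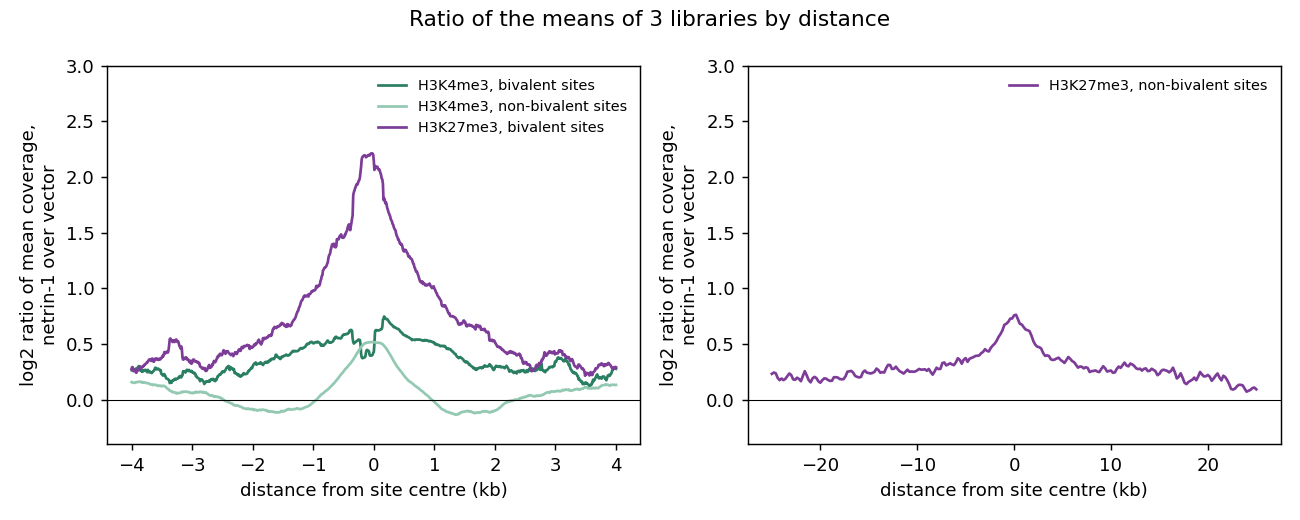
Log2 ratio of the mean coverage of 3 netrin-1 libraries to that of 3 vector libraries (y axis) against distance from the site centre in kb (x axis), at bivalent sites and non-bivalent H3K4me3 sites (left) and non-bivalent H3K27me3 sites (right). The H3K27me3 ratio at bivalent sites is highest near the centre (2.10 within 250 bp, where the narrow double maximum lies). The H3K4me3 ratio at non-bivalent sites is slightly below 0 between 1000 and 2000 bp (-0.09).

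The H3K4me3 log2 ratio at bivalent sites exceeded that at non-bivalent sites by 0.20 (exact permutation p = 0.3, adjusted p = 0.375). Without vector replicate 3 the difference was 0.43, and without vector replicate 1 or 2 it was 0.11 or 0.12. It was 0.12 after division by the flank and 0.11 in a window of 500 bp to each side. For the highest bin it was -0.14 (exact permutation p = 0.5), opposite in sign to the mean over the window.

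Finally, the change of H3K27me3 at bivalent sites was compared with the change of H3K4me3 there. The H3K27me3 log2 ratio within 2000 bp was higher than the H3K4me3 one within 1000 bp by 0.71. This was not distinguishable from chance (exact permutation p = 0.375 over 400 arrangements, adjusted p = 0.375). The null hypothesis is no change in either mark, so the test does not ask directly whether the changes were equal. Without vector H3K4me3 replicate 3 the difference was 0.31, and without netrin-1 H3K27me3 replicate 3 it was 0.42. Over the other settings it ranged from 0.41, without the bins from -350 to 150 bp, to 1.81, for the highest bin, with exact permutation p from 0.185 to 0.54. With 1000 bp to each side for both marks it was 1.08 (exact permutation p = 0.31). These libraries therefore leave open whether the marks differed in the size of their change.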

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

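Of 112 recomputed values over the 7 results, 111 kept their direction and stayed on the same side of the 0.05 threshold, which no comparison of 3 libraries with 3 can pass. The exception was the H3K4me3 difference between bivalent and non-bivalent sites, which was -0.14 for the highest bin instead of 0.20. The cause was not tested. Windows without the bins from -350 to 150 bp, and all alternatives that leave out a library or use replicate pairs for the 3 differences, were chosen after seeing the data. Leaving out 1 library gave log2 ratios of 0.96 to 1.46 for H3K27me3 at bivalent sites and 0.44 to 0.59 at non-bivalent sites. The corresponding ranges for H3K4me3 were 0.36 to 0.95 and 0.24 to 0.52, with the highest values without vector replicate 3. With the replicate block, that is, with same-numbered libraries paired, the H3K27me3 log2 ratios were 1.21 at bivalent and 0.52 at non-bivalent sites, each with p = 0.25 by exact sign flips, the smallest that 3 pairs allow. The H3K4me3 numbers did not pair the libraries, and the block gave 0.61 and 0.36 there. The block changed no direction. It could change no call, because its smallest p is above 0.05 and no main test was below 0.05. Alternatives on tag densities, of both strands or of either, were not run, because the tables analysed hold coverage. The counting error of the mean bin of the central window was at most 0.434%, below the spread between libraries.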

Other observations

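The tests in this part were chosen after the results had been seen, except the division of the centre by the flank and the subtraction of the flank, which had been set beforehand. Flank coverage was also higher in netrin-1 cells in all 4 tables. The flanks lay 3500 to 4000 bp from the centres, or 20000 to 25000 bp for H3K27me3 at non-bivalent sites. H3K27me3 coverage was still falling towards them. In vector cells it was 2.06 from 2000 to 3500 bp and 1.67 in the flank at bivalent sites. At non-bivalent sites it was 1.64 from 10000 to 20000 bp and 1.47 in the flank. The flanks may therefore hold signal of the sites and are not a measured background. At bivalent sites the H3K4me3 flank was 0.678 ± 0.038 in vector and 0.795 ± 0.024 in netrin-1 cells (SD, n = 3). At non-bivalent sites it was 1.15 ± 0.033 and 1.26 ± 0.018 (SD, n = 3). The H3K27me3 flank was 1.67 ± 0.062 and 2.06 ± 0.109 at bivalent sites, and 1.47 ± 0.021 and 1.66 ± 0.055 at non-bivalent sites (SD, n = 3). Every netrin-1 library lay above every vector library in each table. Over both marks the mean log2 difference was 0.21, and permuting the labels separately within each mark gave an exact p of 0.005, the smallest of 400 arrangements. That p treats the marks as independent, which the labels do not state. With the labels of both marks permuted together, the exact p was 0.1, the smallest of 20 arrangements. Both tests were prompted by the separation they measure.

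The H3K27me3 difference at bivalent sites was weighed against 3 technical explanations. One scaling factor per library would move centre and flank alike, but the ratio of centre to flank also separated the cell lines, with a log2 ratio of 0.94. A common gain of the pull-down over a constant background would give both site classes the same log2 ratio after subtraction of the flank, but the bivalent one was higher by 1.18 (0.89 to 1.38 with any 1 library left out), and by 0.86 (0.70 to 0.99) without the bins from -350 to 150 bp. H3K4me3-marked chromatin in the netrin-1 H3K27me3 libraries would add the H3K4me3 shape, but the ratio of the narrow feature to the shoulder was 1.68 to 3.54 in what 3 netrin-1 libraries had over the same vector mean, against 0.790 to 1.09 in the netrin-1 H3K4me3 libraries and 1.29 to 1.52 in the vector ones. The first 2 sets of values argue against a scaling factor per library and a common gain as the whole cause. The third set decides less. With a vector H3K27me3 library left out, the lowest ratio was 1.58, close to the vector H3K4me3 libraries. The narrow feature may also be stacked fragments. Combinations of these explanations, unrecorded batches, the choice of the sites, which is not given, and an effect of netrin-1 itself stay open. The labels do not say how many separately transfected lines each condition had.

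Vector H3K4me3 replicate 3 had central coverage close to the netrin-1 libraries, and its other values went both ways. With the vector label went its flank at non-bivalent sites of 1.11 (other vector libraries 1.17 each, netrin-1 1.24 to 1.28). Its width at bivalent sites of 490 bp (470 and 480 bp, netrin-1 660 to 1020 bp) also did. So did its upstream to downstream ratio there of 1.74 (1.81 each, netrin-1 1.43 to 1.54). Both of these depend on the narrow feature, whose ratio to the shoulder was 1.52 (1.29 each, netrin-1 0.790 to 1.09). With the netrin-1 libraries went its log2 ratio of bivalent to non-bivalent coverage of 0.62 (netrin-1 0.40 to 0.62, other vector libraries 0.12 each), its width at non-bivalent sites of 550 bp (530 to 540 bp, 640 and 700 bp) and its coverage above the flank 500 to 1000 bp from bivalent sites of 7.98 (7.18 to 9.09, 4.66 and 4.38), while its bivalent flank of 0.722 lay between 0.655 and 0.658 in the other vector libraries and 0.770 in the lowest netrin-1 library. A sharper pull-down of the same chromatin could lower the shoulder 1500 to 2500 bp from non-bivalent sites, which was 1.46 (other vector libraries 1.72 and 1.76), but the netrin-1 shoulders of 1.53 to 1.63 were lower too, and the bivalent flank was not lowered. These values leave both a wrong label and a sharper pull-down open, and no biological explanation was tested.

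The narrow double maximum at bivalent sites was one-sided. Coverage 100 to 250 bp upstream of the centre was 1.43 to 2.63 times that at the same distance downstream over the 12 libraries, against 1.01 to 1.03 times at non-bivalent H3K4me3 sites. Between adjacent bins, coverage at -210 bp stepped up by 11.2 to 20.6% of the highest bin in all 12 libraries. At 10 bp the step was -12.5 to -25.2% of the highest bin. No step at non-bivalent H3K4me3 sites exceeded 2.52%. That profile averages an inferred 22595 sites, against 2590 bivalent sites, so edges held by a few sites would be diluted in it. The contrast therefore does not show that such edges are absent at non-bivalent sites. The fixed edges at bivalent sites could come from fragments stacked at fixed positions relative to the centre. Whether a few sites hold them cannot be told apart from many sites sharing a sequence: at 1 fragment per position and strand, at least 121 to 1390 sites would be needed, depending on the library, but whether duplicates were removed is not given in the sources used here.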
